A study of Mus musculus with 6 samples.

How the data were processed

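Total RNA from freshly isolated splenic B cells of 3 mice of the congenic Sle2 strain and 3 B6 mice was labelled with biotin and hybridised to Illumina mouse BeadChips, 1 array per mouse, per the labels. The strain of each mouse, and its number within the strain, came from the sample titles. The deposited table of bead-summary intensities was exported with GenomeStudio, per the submitters' processing notes, which give no version. Its intensities were on a linear scale, had no negative values and differed in distribution between arrays, so they were taken as neither background-subtracted nor normalized by the authors. The deposited table also gave a detection p-value for each probe on each array, per the file headers. The authors' series matrix held a further set of deposited intensities. From the values, these were linear and quantile-normalized with no background subtraction, since all 6 columns shared 1 distribution and each kept the probe ranks of its own array. The series matrix medians lay between 53.6264 and 53.6581. The normalization method's name is not given in the sources used here.

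Of 45281 probes, 34885 had 1 gene symbol in the platform annotation supplied with the series, 18 had several and 10378 had none. Symbols were updated by gene identifier through a RefSeq gene table of mouse assembly GRCm38.p6, which held the genes of 34807 probes and lacked those of 78. That table also gave the chromosome and the order of the genes. The deposited files name no genome build, so no coordinates are given. Probes with several symbols or none were fitted but not named.

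Intensities were background-corrected with normexp, using the detection p-values to recover the 936 negative controls, with an offset of 16, then quantile-normalized and log2-transformed (neqc, limma 3.58.1 in R 4.3.3). Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept, which left 17861 probes. A gene was represented by its kept probe with the highest mean over the 6 arrays, which gave 9297 genes. Strains were compared with lmFit and eBayes at default settings, two-sided, with Benjamini-Hochberg adjustment over all kept probes, and a gene was called at an adjusted p under 0.05. Fold changes are Sle2 minus B6 on the log2 scale with limma's standard error (SE), and means carry the SD of 3 mice. Where a probe was not detected on any array of a strain, the difference is a lower bound. It sets the brighter strain's mean against the mean, over the dimmer strain's arrays, of the higher of the probe's own value and the lowest value among detected probes. Arrays carry no read depth, and their number limits the precision.

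Calls were compared between chromosomes with Fisher's exact test, two-sided, over the 9280 tested genes that had a chromosome, with Benjamini-Hochberg adjustment over the chromosomes. There were 30 gene lists, tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 30 lists, with an estimated correlation and fry beside it. With an estimated correlation, camera uses the residual degrees of freedom of the arrays, which are few. This raises p-values even at the same correlation. Named genes were chosen by rule. They were the 10 genes with the largest higher and the 10 with the largest lower differences among called genes whose strains did not overlap and whose symbols were not predicted or clone names. Faah, Cdkn2c, Rag1, Rag2, Cd5 and Dntt were always named. To these were added up to 4 members with the smallest p from each list, all called members where 6 or fewer were called, and the 6 chromosome 4 genes with the smallest p. The groups, lists, rule, tests and most alternatives were fixed before the data were examined.

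The alternatives were no background correction, scaling to equal medians, the series matrix values, no filter, a strict filter (detection p-value under 0.01 on all 6 arrays), a trended robust prior, array weights, the mean of all kept probes of a gene, the mouse number as a block, each mouse left out in turn, other thresholds and other set tests. A fit with each array's Xist signal as a covariate, a count of genes with any called probe, all alternatives for chromosome 9, and a comparison of chromosome 2 that leaves out chromosomes 4 and 9, were added after the data were seen. The interval tested on chromosome 9 was the 10 Mb window with most calls. A narrower span bounded by called genes was also tried, and both are given.

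The fit was tested on simulated data for the comparison of Sle2 with B6, drawn for all kept probes of the 9297 genes from their means and SDs, with 200 genes changed. It recovered 13 of 50 genes changed by 0.5 on the log2 scale, 40 of 50 changed by 1, 49 of 50 changed by 2 and 50 of 50 changed by 3, with 7 calls among unchanged genes. With no gene changed it made 0 calls. In a simulation of 30 lists, with each gene drawn independently, camera called 5 of 5 lists shifted by 0.5 and 2 of 25 unshifted lists. It therefore does not check camera on lists whose genes vary together, such as the erythroid list (estimated correlation 0.426).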

Results

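Gene expression was measured in splenic B cells of Sle2 and B6 mice, with 3 mice per strain and 1 Illumina BeadChip per mouse. Sle2 mice carry a lupus susceptibility segment of chromosome 4 from the NZM2410 strain on a B6 background. The comparison asks which transcripts differ in peripheral B cells that carry this segment, and the series title points to Faah, receptor revision and B-1 cells. Median intensities before normalization were 56.7, 53.6 and 53.6 on the Sle2 arrays and 52.1, 50.4 and 51.7 on the B6 arrays. Between 17417 and 17923 probes were detected per array.

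Faah, which encodes the fatty acid amide hydrolase that breaks down the endocannabinoid anandamide, was higher in Sle2 B cells by 2.33 on the log2 scale (SE 0.278), a 5.03-fold difference. The largest other increases were Cpne4, a calcium-dependent phospholipid-binding protein, which was at least 10.9-fold higher, and Fgr, a Src family kinase, which rose by 3.04. By the brightest kept probe of each gene, the largest decreases were Tceanc2 (-2.78) and Med18 (-2.77), a subunit of the Mediator complex. Cdkn2c, an inhibitor of the kinases Cdk4 and Cdk6, fell by 1.55 on the log2 scale. In all, 97 of 9297 tested genes were called by limma at an adjusted p under 0.05, of which 61 were higher and 36 lower in Sle2. All 97 separated the 3 Sle2 mice from the 3 B6 mice without overlap, as did 24.2% of all tested genes, where chance gives 10%. At least a 2-fold difference was reached by 28 of the called genes, 15 higher and 13 lower. Of 34 further kept probes of called genes, 28 had the sign of the representative probe, 11 were called in the same direction and 0 in the opposite one. With arrays scaled to equal medians, 219 genes were called higher and 26 lower, so 89.4% of calls were higher against 62.9% with quantile normalization, and the median of all genes moved from 0.02 to 0.14 on the log2 scale. The count of called genes was 28, 32 and 29 without Sle2 mouse 1, 2 and 3, and 56 and 38 without B6 mouse 2 and 3. With each array's Xist signal as a covariate it was 51, of which 46 were among the 97.

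**Figure D1:**
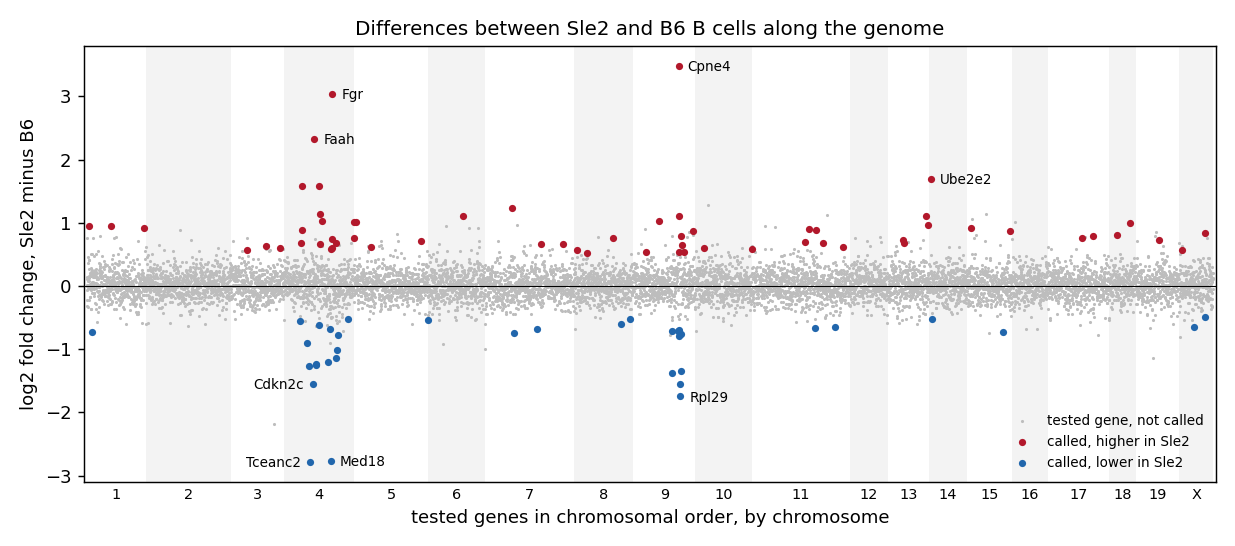
Log2 fold change (Sle2 minus B6) of each tested gene on the autosomes and X, in chromosomal order, with called genes in red (higher in Sle2) or blue (lower). Called genes gather on chromosome 4, with 30, and on chromosome 9, with 18.

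Faah was measured by a pair of detected probes, with similar differences of 2.33 (adjusted p = 0.00718) and 2.27 (adjusted p = 0.00743). The other Faah probes were not detected on any array of either strain (differences of 0.27, 0.10 and -0.09) and were not tested. Its normalized value was 8.91 ± 0.07 (SD, n = 3) in Sle2 and 6.58 ± 0.67 (SD, n = 3) in B6. The B6 spread came from mouse 1, at 7.35, against 6.29 and 6.11 in the others, and all 3 Sle2 mice lay above all 3 B6 mice. The exact two-sided permutation p was 0.1 for each probe, the smallest that 3 against 3 allows. Cnr2, the cannabinoid receptor expressed on B cells, rose by 0.68 (SE 0.102, adjusted p = 0.0216). These were the 2 called genes of 11 tested in the endocannabinoid list, and also the 2 called when adjusted over the list alone; both lie on chromosome 4. Daglb (0.27) and Gde1 (0.23), enzymes of endocannabinoid synthesis, did not pass the test. The list did not shift as a set (median 0.06, camera adjusted p = 0.0874). Faah missed the threshold with no filter on dim probes (adjusted p = 0.0694) and with a trended robust prior (adjusted p = 0.0566), in a range of 0.000105 to 0.0694 over its alternatives. Cnr2 missed it without Sle2 mouse 1, 2 or 3 (adjusted p = 0.112, 0.0969 and 0.0586) or B6 mouse 3 (adjusted p = 0.0893), and its other kept probe was at 0.45 (adjusted p = 0.083); the list passed without Sle2 mouse 2 (adjusted p = 0.0476) or B6 mouse 1 (adjusted p = 0.0254).

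**Figure D2:**
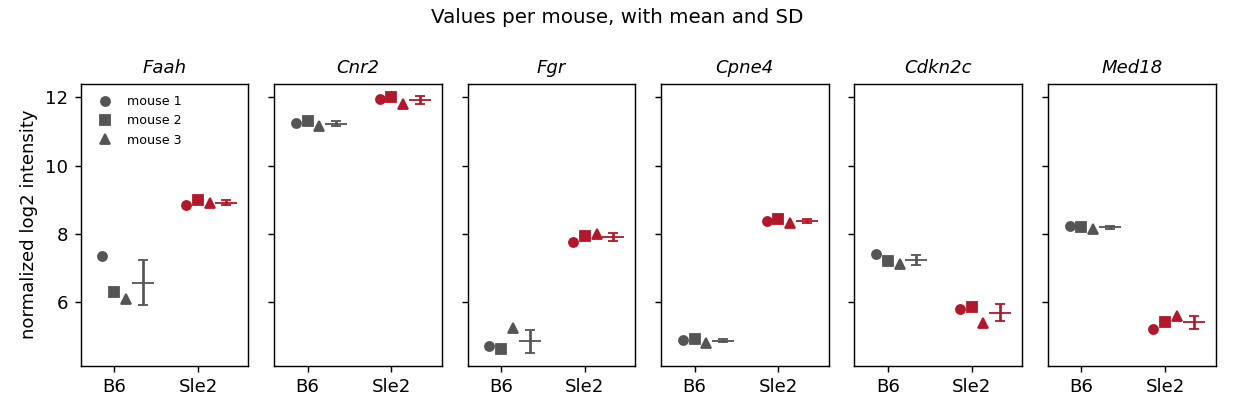
Normalized log2 intensity of 6 genes in each mouse (symbols), with the mean and SD of 3 mice per strain (horizontal mark and bars). Faah is higher in every Sle2 mouse, and B6 mouse 1 lies above the other B6 mice at 7.35.

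Chromosome 4 held 30 of the 97 called genes among its 575 tested genes, 15 higher and 15 lower. Its share of called genes was 5.22%, against 0.77% elsewhere (odds ratio 7.09, Fisher's exact adjusted p = 1.2e-12). Besides Faah and Fgr, the larger increases there were Alad (1.58), an enzyme of haem synthesis, Hyi (1.58) and Guca2b (1.14). The other kept probe of Hyi was at -0.14 (adjusted p = 0.549), and the mean of both was 0.72 (adjusted p = 0.0112). Fgr was detected in 1 of the 3 B6 mice. Besides Tceanc2, Med18 and Cdkn2c, the larger decreases were Ccdc163 (-1.24), Prdx1 (-1.24), a peroxiredoxin, and Wdr78, which was not detected in Sle2 and was at least 1.69-fold lower. Tceanc2 was detected in 1 of the 3 Sle2 mice. With the series matrix values Guca2b was at 0.68 and Ccdc163 at -0.77, and without background correction Guca2b was at 0.74 and Ccdc163 at -0.83, both still called. The 6 chromosome 4 genes with the smallest p were Med18, Fgr, Tceanc2, Hyi, Alad and Wdr78. By gene order in GRCm38.p6, the called genes ran from Tmem38b to Perm1 but were unevenly spread. The adjacent 10 Mb windows Ube2u to Faf1, Spata6 to Hivep3, Scmh1 to Ptp4a2 and Pef1 to Aldh4a1 held 3, 7, 2 and 10. The next window, Rcc2 to H6pd, held 0 among 50 tested genes, and the last, Errfi1 to Noc2l, held 3. Aco1 to Rnf20, before Tmem38b, held 0 among 72. The odds ratio stayed above 1 and past the threshold under all 19 alternatives. It fell to 2.71 with median scaling, 2.83 with a trended robust prior, 4.06 with the series matrix values, 4.49 without background correction and 3.73 at an adjusted p under 0.1, and was 10.95 with the Xist covariate. It was 20.7, 15.5 and 19.1 without Sle2 mouse 1, 2 and 3, and 3.65 and 12.6 without B6 mouse 1 and 3.

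Chromosome 9 held the next largest share, with 18 called genes among 513 tested, 9 higher and 9 lower (odds ratio 4.00, Fisher's exact adjusted p = 5.39e-05). Of these, 13 lay in the window from Nck1 to Map4, which had 92 tested genes. Cpne4, detected in no B6 mouse, is among them, as are Rpl29 (-1.75), a ribosomal protein gene, Dusp7 (-1.55), a phosphatase of MAP kinases, and Parp3 (-1.35). The other kept probe of Rpl29 was at -4.29 (adjusted p = 6.97e-06), and the mean of both was -3.02. Bckdhb (-1.38), a subunit of the branched-chain keto acid dehydrogenase, lies outside it, and was at -0.88 without background correction and -0.80 with the series matrix values. The chromosome 9 odds ratio was 2.35 without B6 mouse 1, 2.47 with median scaling, 2.07 with a trended robust prior, 2.56 without background correction and 2.04 at an adjusted p under 0.1. The other kept probes of Mrpl3 (-0.56, adjusted p = 0.0721, against 0.54) and Tent5a (0.09, adjusted p = 0.81, against -0.72) had the opposite sign to the representative probe. Chromosome 2 had 0 called genes by limma among 698 tested, fewer than elsewhere (Fisher's exact adjusted p = 0.00565), and 110 (15.8%) at an unadjusted p under 0.05, against 15.5% of the genes not called on chromosomes other than 4 and 9. Chromosomes 12 and 16 also had 0 called genes by limma, among 310 and 291 tested, with 51 and 40 at an unadjusted p under 0.05. Part of the chromosome 2 contrast comes from chromosomes 4 and 9, without which it was 0 against 49 of 7494 (0.654%, unadjusted Fisher's exact p = 0.0199). Outside chromosomes 4 and 9, 49 of 8192 tested genes were called, 37 higher and 12 lower. The largest there were Ube2e2 (1.69), a ubiquitin-conjugating enzyme, Ffar2 (1.24), a receptor for short-chain fatty acids, Srgap3 (1.10) and Pde4d (1.10), a cAMP phosphodiesterase. The other kept probe of Pde4d was at 0.11 (adjusted p = 0.617), and the mean of both was 0.61 (adjusted p = 0.0699). With no filter Ube2e2 (adjusted p = 0.0555), Srgap3 (adjusted p = 0.091) and Pde4d (adjusted p = 0.138) missed the threshold, as did the gene Pde4d with the Xist covariate (adjusted p = 0.0615). Pde4d missed it without any one of Sle2 mouse 1, 2 and 3 (adjusted p = 0.136, 0.145 and 0.119) or B6 mouse 1 and 3 (adjusted p = 0.0625 and 0.141), and Srgap3 without Sle2 mouse 1, 2 or 3 (adjusted p = 0.0898, 0.0823 and 0.0941).

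Marginal zone B cell markers rose as a set, with a median of 0.36 over 13 tested genes (camera adjusted p = 0.00756, fry adjusted p = 0.0231). With the estimated correlation, which was 0.00349 and below the preset 0.01, the camera adjusted p was 0.498. Cd1d1 (0.56), which presents lipid antigens, and Rgs10 (0.67), a regulator of G protein signalling, were called. Dusp16 (0.62) and Cr2 (0.62), the complement receptor also known as CD21, were higher but not called. Adjusted over the marginal zone list alone, 7 genes were higher, against 2 over all genes. In the same arrays the T cell and erythroid lists rose too, each with a median of 0.33. For both, the camera adjusted p was 0.0142, and 0.702 with an estimated correlation. Cd1d1 and Rgs10 missed the threshold without Sle2 mouse 1 (adjusted p = 0.136 for both), Sle2 mouse 2 (0.122 and 0.133), Sle2 mouse 3 (0.153 and 0.172), B6 mouse 2 (0.0699 and 0.128) or B6 mouse 3 (0.127 and 0.147), and Cd1d1 without B6 mouse 1 (0.0557). Both missed it with the Xist covariate (0.053 and 0.074), and Rgs10 with no filter (0.101). Transitional and immature B cell markers fell as a set, with a median of -0.26 over 8 genes (camera adjusted p = 0.0451; adjusted p = 0.498 with an estimated correlation). None of its members was called over all genes and 3 were lower when adjusted over the list alone. Bmf (-0.63), Cd93 (-0.61) and Vpreb3 (-0.50) had the smallest p, and Il7r (0.28) went the other way. That call was lost without Sle2 mouse 1 (adjusted p = 0.082), B6 mouse 1 (adjusted p = 0.0699) or B6 mouse 3 (adjusted p = 0.0504), and with the mean of all kept probes (adjusted p = 0.109).

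**Figure D3:**
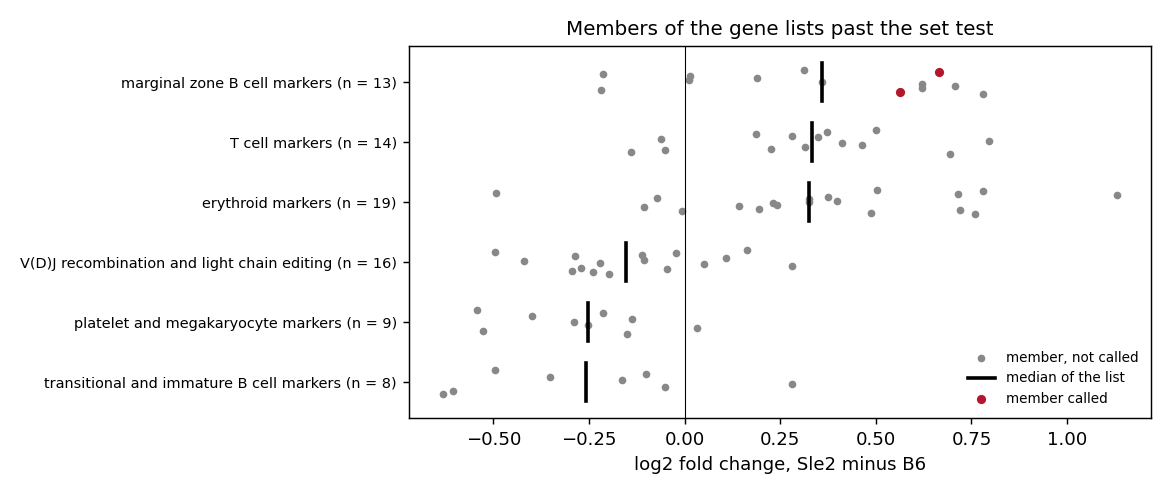
Log2 fold change (Sle2 minus B6) of the tested members of the 6 gene lists past the set test, with the list median as a black bar and called members in red. The medians run from -0.26 for transitional and immature markers to 0.36 for marginal zone markers.

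Follicular B cell markers did not shift (median -0.05 over 10 genes, adjusted p = 0.255), with Klf2 at -0.38, Ccr7 at -0.25, Fcrl1 at -0.20 and Icosl at -0.25. With single mice left out the list median ran from -0.14 to 0.02. Icosl ran from -0.37 to 0.30 over its alternatives. B-1 cell markers did not shift either (median 0.13 over 16 genes, adjusted p = 0.7), though their median ran from 0.0018 to 0.28 with single mice left out. Cd5, the marker that defines B-1a cells, was not detected on any array. It has 1 probe in the annotation used, so low expression and an insensitive probe cannot be told apart. Adjusted over the list alone, 3 B-1 genes were higher and 2 lower, against 0 called over all genes, with Arid3a at -0.55, S100a6 at -0.36, Pdcd1lg2 at 0.43 and Bhlhe40 at 0.30. Plasma cell markers had a median of 0.17 over 19 genes (adjusted p = 0.156), with Creld2 at 0.36, Derl3 at 0.66, Hsp90b1 at 0.28 and Edem2 at 0.34, and passed without B6 mouse 1 (adjusted p = 0.0498). Germinal centre markers had a median of -0.08 over 7 genes (adjusted p = 0.5), with Bcl6 at -0.21, Fas at 0.23, Mef2b at -0.21 and S1pr2 at -0.31. Leaving out single mice moved this median between -0.15 and 0.04, and S1pr2 between -0.58 and -0.02. Of the immunoglobulin constant regions only Ighg1 was tested, at -0.47, and the list did not pass (adjusted p = 0.156).

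The list of V(D)J recombination and light chain editing genes, which bears on receptor revision, fell as a set by a small amount, with a median of -0.15 over 16 genes (camera adjusted p = 0.0451; adjusted p = 0.498 with an estimated correlation). Rag1 and Rag2, which encode the recombinase, and Dntt, the terminal transferase, were not detected on any array, so the shift does not include them. Each has 1 probe in the annotation used, which could also be insensitive. No member was called over all genes or when adjusted over the list alone, where both counts were 0. Lig4 (-0.42), a ligase of end joining, Vpreb3 (-0.50), Ikzf3 (-0.27) and Irf8 (-0.22) had the smallest p. The call was lost without Sle2 mouse 1 (adjusted p = 0.0558), Sle2 mouse 3 (adjusted p = 0.0571), B6 mouse 2 (adjusted p = 0.0632) or B6 mouse 3 (adjusted p = 0.0536), with median scaling (adjusted p = 0.0627) and with the mean of all kept probes (adjusted p = 0.0513). B cell receptor signalling genes did not shift (median 0.00 over 27 genes, adjusted p = 0.667), with Cd81 at 0.36, Siglecg at -0.35, Dok3 at 0.35 and Syk at -0.32, and the mean and test had the opposite sign to the median.

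Among cell cycle genes, Cdkn2c was the 1 called gene of 17 tested in the list of cyclin-dependent kinase inhibitors and G1 control, with 7.24 ± 0.15 (SD, n = 3) in B6 and 5.70 ± 0.25 (SD, n = 3) in Sle2 (SE 0.143, adjusted p = 0.00158). Its other kept probe was not detected in Sle2 and was at least 2.88-fold lower (adjusted p = 2.89e-05). Adjusted over the list alone, 3 genes were lower. Cdkn2d (-0.44), Ccne1 (-0.44) and Cdkn1c (0.37) did not pass over all genes. The list had a median of -0.13 (camera adjusted p = 0.0526), which without Sle2 mouse 2 (adjusted p = 0.0476) or B6 mouse 2 (adjusted p = 0.0246) passed the threshold. Proliferation genes did not shift (median 0.07 over 21 genes, adjusted p = 0.99), and their test had the opposite sign to the median; Mcm3 was at -0.23, Tk1 at 0.21, Mcm7 at -0.23 and Aurka at 0.17.

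Some lists of markers of other cell types also passed the set test at the preset correlation. T cell markers rose as a set, with a median of 0.33 over 14 genes (camera adjusted p = 0.0142; adjusted p = 0.702 with an estimated correlation), led by Bcl11b (0.69), Zap70 (0.50), Cd3g (0.41) and Icos (0.35). Erythroid markers rose with a median of 0.33 over 19 genes (camera adjusted p = 0.0142; adjusted p = 0.702 with an estimated correlation), with Sptb at 0.71, Slc4a1 at 1.13, Tspan33 at 0.50 and Tfrc at -0.49. In B6 mouse 3, Xist was detected (5.89) along with a high Y-linked Eif2s3y (8.67). Platelet markers fell with a median of -0.25 over 9 genes (camera adjusted p = 0.0437; adjusted p = 0.702 with an estimated correlation), with Clec1b at -0.53, Vwf at -0.54, Itga2b at -0.29 and Ppbp at -0.40. No member of the T cell, erythroid or platelet lists was called over all genes. Adjusted over the list alone, 3 T cell genes and 5 erythroid genes were higher, and 1 erythroid and 2 platelet genes were lower. The platelet decrease rested on B6 mouse 3, without which the median was 0.15 (adjusted p = 0.989); it also missed the threshold without Sle2 mouse 2 (adjusted p = 0.0849). The erythroid call was lost without Sle2 mouse 1 (adjusted p = 0.0522) or B6 mouse 2 (adjusted p = 0.06). With median scaling and with the strict filter, the T cell list (adjusted p = 0.0627 and 0.0945) and the erythroid list (adjusted p = 0.0858 and 0.19) missed the threshold, and the platelet list did with no filter (adjusted p = 0.0955).

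The remaining cell type lists did not pass with all mice. Natural killer markers had a median of 0.34 (adjusted p = 0.156; Prf1 0.47, Klrg1 0.27, Klre1 0.52, Klrd1 0.37) and passed without Sle2 mouse 3 (adjusted p = 0.0268) or B6 mouse 1 (adjusted p = 0.0498). Monocyte and macrophage markers had a median of -0.12 (adjusted p = 0.156; Spic -0.41, Lyz2 0.44, Hmox1 -0.51, Marco 0.35) and passed without Sle2 mouse 1 (adjusted p = 0.0119) or B6 mouse 2 (adjusted p = 0.0146). Neutrophil markers had a median of 0.22 (adjusted p = 0.177), with Ltf at 0.86, Camp at 0.77, Ngp at 0.37 and Lcn2 at 0.56. Without B6 mouse 3 that median became 0.72 (camera adjusted p = 3.6e-06). That p-value uses the preset correlation of 0.01, while 0.561 was estimated for this list with all mice. Relative to the mean of the arrays, the list stood at -0.74, -0.30 and 0.57 in B6 mice 1, 2 and 3. Dendritic cell markers had a median of 0.18 (adjusted p = 0.839; Xcr1 -0.33, Ly6d -0.31, Itgae 0.59, Siglech 0.49). Of the stromal and endothelial markers 2 were tested, Pecam1 (-0.31) and Igfbp7 (0.64), with a median of 0.16, a test of the opposite sign and an adjusted p = 0.868.

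Genes of the type I interferon response had a median of 0.19 over 24 genes, which did not pass (camera adjusted p = 0.0526), with Isg20 at 0.64, Oasl1 at 0.48, Rsad2 at 0.76 and Eif2ak2 at 0.28. Relative to the mean of the arrays, it stood at -0.15, -0.01 and 0.49 in Sle2 mice 1, 2 and 3. In B6 mice 1, 2 and 3 it stood at -0.34, -0.03 and 0.05, so only Sle2 mouse 3 lay above all B6 mice. With single mice left out the median ran from 0.0358 to 0.39. The list did not pass without Sle2 mouse 3 or B6 mouse 1. It passed without Sle2 mouse 1 (camera adjusted p = 0.00044), Sle2 mouse 2 (adjusted p = 0.0185), B6 mouse 2 (adjusted p = 0.0146) or B6 mouse 3 (adjusted p = 0.00826). Each of these fits used the preset correlation of 0.01, while 0.666 was estimated for the list with all mice. Apoptosis and survival genes had a median of 0.07 (adjusted p = 0.366; Bcl2a1d 0.42, Bid 0.39, Traf1 0.39). Toll-like receptors and adaptors had a median of 0.11 (adjusted p = 0.156; Cd180 0.31, Ly96 0.27, Irf3 0.24, Tlr7 0.31). Activation and immediate early genes had a median of 0.06 (adjusted p = 0.963; Cd83 -0.38, Zfp36 -0.41, Tnfaip3 0.28, Fos 0.28). Class II antigen presentation genes had a median of -0.04 (adjusted p = 0.255; Ifi30 -0.48, Cd40 0.31, Ctsh -0.22, H2-Ob -0.17). Unfolded protein response genes had a median of 0.12 (adjusted p = 0.0915; Pdia3 0.31, Dnajb9 0.30, Atf4 0.26), and heat shock genes one of 0.14 (adjusted p = 0.0799; Dnajb1 0.37, Dnaja1 0.30, Ier3 0.25). The former passed without B6 mouse 1 (adjusted p = 0.0395), and the latter without Sle2 mouse 2 (adjusted p = 0.0394) or B6 mouse 3 (adjusted p = 0.0433). Oxidative phosphorylation genes had a median of -0.08 (adjusted p = 0.156; Ndufb3 -0.41, Ndufa5 -0.44, Ndufa6 -0.32, Ndufb7 -0.37) and passed without B6 mouse 1 (adjusted p = 0.0498). Cytosolic ribosomal protein genes had a median of -0.01, a mean of 0.02, a test with the sign of the median and an adjusted p = 0.99 (Rplp0 0.57, Rpl24 0.20, Rpl4 0.22, Rpl30 -0.26). Sex-linked genes had a median of 0.01, a mean of -0.03, a test with the sign of the mean and an adjusted p = 0.868 (Uty -0.03, Xist -0.25, Eif2s3y 0.10, Kdm5d 0.04).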

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

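All tests in this part except the counts over other splits of the samples were chosen after the result was seen. A signal outside the named genes was seen in 45 called probes that have no gene name in the annotation used here, 20 higher and 25 lower in Sle2.

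Calls gathered on chromosome 4, the chromosome of the donor segment. Arrays designed on B6 sequence can lose signal where donor bases differ under a probe, but such mismatches lower the Sle2 value, so the 15 called genes that were higher in Sle2 argue against them for those genes. The increase of Hyi and Atpif1 rests on 1 probe, since their other kept probes were at -0.14 (adjusted p = 0.549) and 0.03 (adjusted p = 0.944). Those of Faah (2.27), Cnr2 (0.45) and Gng10 (0.71) were higher. The remaining chromosome 4 genes called higher, Fgr and Alad among them, had 1 kept probe each, so no second probe bears on them. For Cdkn2c, Tceanc2 and Tcea3, every other kept probe was lower and called too, the least at -0.79, which argues against a mismatch under 1 probe, while the other probe of Tmem38b was at 0.30 (adjusted p = 0.339), so a mismatch may account for that gene. For the 11 lower genes measured by 1 probe, base differences and lower expression cannot be told apart, because probe sequences were not compared with donor sequence. Expression differences of the donor segment itself remain an open biological hypothesis.

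Calls also gathered on chromosome 9, which the labels do not name as donor: the densest run of 50 tested genes held 12 calls, against at most 7 in 10000 random placements of the calls outside chromosome 4 (permutation p = 1e-04, the smallest they can give), and 9 of the 18 called genes of the chromosome were higher, which argues against mismatches for those, though the other kept probe of Mrpl3, one of them, was at -0.56 (adjusted p = 0.0721). Among its lower genes, the other kept probes of Rpl29 (-4.29, adjusted p = 6.97e-06) and Mapkapk3 (-0.85 and -0.80, adjusted p = 0.0429 and 0.013) were lower too, and that of Tent5a was at 0.09. A candidate explanation is a second stretch of donor origin: among genes not called in the window from Nck1 to Map4, 25 of 79 had an unadjusted p under 0.05, against 15.5% on chromosomes other than 4 and 9 (Fisher's exact p = 0.000448), and 14 of 40 in the narrower span from Tmem108 to 1700102P08Rik, whose ends were set by called genes (Fisher's exact p = 0.00313). Shares as high were seen in the chromosome 9 windows from Senp6 to Tmed3 (8 of 20) and Cx3cr1 to Ppp2r3d (9 of 27), and in 2 of 148 windows with at least 20 such genes on chromosomes other than 4 and 9, so the extent of any such stretch is open, genotypes were not analysed here, and co-regulation of neighbours was not tested.

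T cell and erythroid markers were called higher in Sle2 and platelet markers lower with a preset correlation, and none of these calls held with an estimated one (adjusted p = 0.702 for each). The estimates were 0.25, 0.426 and 0.515, but that setting also leaves few degrees of freedom. The loss thus cannot be put down to correlation alone. A lower share of B cells in the Sle2 preparations would raise markers of every other type only if all of those types filled its place. A count over lists tests that case alone, and 6 of the 8 lists of other cell types had a median above 0. Of these only the T cell and erythroid lists passed the test, and the stromal and endothelial list held 2 tested genes of opposite sign. Of the lists with a median below 0, the platelet list was called lower. Its median was 0.15 without B6 mouse 3, which had both Xist (5.89) and Y-linked Eif2s3y (8.67), and the call was lost without Sle2 mouse 2 (adjusted p = 0.0849). The monocyte and macrophage list (-0.12) did not pass with all mice but was called lower without Sle2 mouse 1 or B6 mouse 2. An increase of all other cell types thus cannot be told apart from differences between single mice, and an increase of single types was not tested. B cell receptor signalling genes did not fall as a set (median 0.00 over 27 genes, camera adjusted p = 0.667), but a small loss of B cells could go unseen. More T cell RNA in the Sle2 preparations was not tested and stays open; 2 of the 14 T cell markers are also in other lists. The brightest T cell markers, Cd2 (10.98 in Sle2, 11.12 in B6) and Cd8b1 (10.17 and 10.23), were not higher, though mouse B cells also express Cd2. The next, Thy1 (7.05 and 6.68), was at 0.37 (adjusted p = 0.242). The B cell isolation named in the labels should remove T cells, yet Cd8b1 lay far above the lowest detected values (4.90 to 4.95). The erythroid marker Hbb-bs (14.33 in Sle2, 14.01 in B6) and the macrophage marker Slc40a1 (12.84 and 13.13) were bright too. The preparations of both strains thus cannot be taken as B cells alone.

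Regrouping the 6 arrays into 3 and 3 gives 10 splits, too few for a share under 0.05. The real split gave 97 called genes, the most of any (1 of 10 splits as large), and the highest other split gave 2. On chromosome 4 it gave 30, again 1 of 10 splits as large, against 1 in the highest other. For gene lists it gave 6 called, 5 of the 10 splits gave as many, and the highest other split gave 12.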

How the results depend on the processing

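The fit with Xist as a covariate, the count over any probe and all chromosome 9 alternatives were chosen after the data were seen; the other alternatives were planned. The odds ratios of chromosome 4 (2.71 to 20.7) and chromosome 9 (2.04 to 5.77) kept their direction and stayed past the threshold under all 19 alternatives. The 22 other called named genes kept direction and call in 311 of 344 checks, lost the call in 33 and reversed in 0. Array weights, the strict filter and the 1.5-fold threshold left the number of called genes within 1.5 times of 97. Slide could not be used as a block, since the column names give none, so that fit was not run. The sample titles number the mice of each strain and name no pairing. Deviations of same-numbered mice correlated at 0.20, 0.13 and 0.04. Only Sle2 mouse 3 correlated better with another number, at 0.07 with B6 mouse 2. A batch shared by number is thus neither shown nor excluded. With the replicate block 72 genes were called, 60 of them among the 97, and of the lists it newly called the interferon response (0.19); Cd1d1 (adjusted p = 0.0645) and Rgs10 (adjusted p = 0.0715) were not called with it, and the other called named genes were. For arrays the limit is signal over background: 10 called genes have only a bound, and Rag1, Rag2, Cd5 and Dntt lie below detection.

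The number of called genes was 173 without background correction (105 higher, 68 lower), 245 with median scaling (219 higher), 187 with the series matrix values (115 higher, 72 lower), 56 without a filter (30 higher), 285 with a trended robust prior (174 higher, 111 lower), 51 with the Xist covariate (32 higher, 19 lower) and 250 at an adjusted p under 0.1 (152 higher, 98 lower). Counting any probe gave 57 lower. Leaving out each mouse in turn gave 28 to 143 called genes, 14 to 95 higher and 13 to 48 lower; fewer samples can lower a count, yet the 143, with 95 higher, came without B6 mouse 1. Faah stayed at 2.33 but missed the threshold without a filter and with a trended robust prior (range of adjusted p over its alternatives 0.000105 to 0.0694). Causes were not tested unless stated.

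Of the 6 called lists, 0 held with an estimated correlation: marginal zone 0.36, T cell 0.33, erythroid 0.33, V(D)J and editing -0.15, transitional -0.26 and platelet -0.25, all with unchanged medians. The smallest adjusted p over the alternatives, each at the preset correlation, was 0.000345, 0.00151, 3.6e-06, 0.0296, 0.0013 and 0.000345, in that order. For the marginal zone list the estimated correlation was 0.00349, below the preset 0.01, so a higher correlation does not account for its loss. Its unadjusted camera p was 0.000252 with the preset correlation and 0.0192 with the estimated one. The few residual degrees of freedom of the latter setting raise p-values, so a loss with it does not by itself speak against a list. By fry 2 lists passed, marginal zone and, newly, apoptosis (0.0691); T cell 0.33, erythroid 0.33, V(D)J -0.15, transitional -0.26 and platelet -0.25 did not. Median scaling, which moves the median of all genes to 0.14, ended the calls of T cell (0.41), erythroid (0.40) and V(D)J (-0.0322) and brought in the list of kinase inhibitors and G1 control, whose median of 0.0258 lies below that of all genes. The strict filter ended T cell (0.37) and erythroid (0.24) and brought in kinase inhibitors (-0.13) and the unfolded protein response (0.12). Without a filter the platelet list (-0.15) was lost and Toll-like receptors (0.11) and heat shock (0.11) passed. The mean of all kept probes ended V(D)J (-0.14) and transitional (-0.26), and brought in kinase inhibitors (-0.12), endocannabinoid (0.11), heat shock (0.16) and unfolded protein response (0.12). Array weights brought in endocannabinoid (0.0740). The interferon response passed without background correction (0.15), with series matrix values (0.16) and with the Xist covariate (0.22). Other causes of these changes were not tested.

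Leaving out each mouse, between 5 and 10 lists passed, 10 without B6 mouse 1. List medians that crossed the threshold in at least 1 such fit ranged as follows: V(D)J -0.21 to -0.14, transitional -0.42 to -0.12, erythroid 0.27 to 0.52, kinase inhibitors -0.15 to -0.0375, endocannabinoid 0.0647 to 0.15, heat shock 0.11 to 0.18, unfolded protein response 0.0845 to 0.15, plasma cell 0.13 to 0.23, oxidative phosphorylation -0.10 to -0.0017, interferon 0.0358 to 0.39, monocyte -0.24 to 0.0355, natural killer -0.00038 to 0.57 and neutrophil 0.0179 to 0.72. The platelet list ran from -0.52 to 0.15, with the positive value without B6 mouse 3.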

Other observations

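No test in this part was planned, and values are given without explanation. Some called genes outside the naming rule, chosen after their values were seen, encode receptors or other surface proteins, and they went both ways. Ackr2 (0.87), Ackr3 (0.96, detected in 1 of 3 B6 mice), Trem1 (0.80) and Sema7a (1.02), a membrane semaphorin, were higher in Sle2, though the other kept probe of Trem1 was at 0.19 (adjusted p = 0.544). Ifnlr1, a receptor subunit for type III interferons on chromosome 4, was not detected in Sle2 and was at least 2.04-fold lower, and Ngfr fell by 0.67 on the log2 scale.

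One probe with no gene name was lower in Sle2 by more than any named gene (log2 difference -6.34, SE 0.405, adjusted p = 0.000154), at 12.02 ± 0.11 (SD, n = 3) in B6 and 5.68 ± 1.00 (SD, n = 3) in Sle2.

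Xist was bright in Sle2 mouse 3 (10.93) and B6 mouse 2 (10.13), near background in Sle2 mice 1 and 2 (4.36 and 4.30) and B6 mouse 1 (4.33), and at 5.89 in B6 mouse 3. Eif2s3y, on the Y chromosome, was at 8.33, 8.39 and 5.36 in Sle2 mice 1, 2 and 3 and at 8.44, 4.65 and 8.67 in the B6 mice. The B6 mouse 3 array thus had Xist above detection together with Y-linked signal, unlike the others with high Eif2s3y, and in Sle2 mouse 3 the lower Eif2s3y value was also above detection. By these genes, Sle2 mouse 3 and B6 mouse 2 look female, and Sle2 mice 1 and 2 and B6 mouse 1 look male. Both strains thus appear to hold mice of both sexes. The sexes of the mice are not stated in the labels used here, and whether these samples were mixed was not tested.

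B6 mouse 1 stood apart from the other arrays on the second principal component (-27.4, against -3.27 to 11.8), which held 22.2% of the variance. It had 86 probes without a gene name more than 1 above every other array on the log2 scale, and 16 probes with a name. The interferon list was highest in Sle2 mouse 3, at 0.49 relative to the mean of the arrays, and lowest in B6 mouse 1, at -0.34.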
